A study of Drosophila melanogaster with 36 samples.

How the data were processed

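RAMPAGE, a method that sequences the 5′ ends of capped RNA to map transcription start sites, was applied to whole Drosophila melanogaster of the y; cn bw sp strain at 36 stages of the life cycle. Per the labels' protocols, 5′-monophosphate RNA was digested with an exonuclease, and 5′-complete cDNA was enriched by template switching and by cap trapping. Animals were pooled within a stage, and each stage gave 1 library. The stages were 24 hourly embryo windows, 5 larval stages, 5 pupal stages, and 1 library each of adult males and females. Embryos came from 1 h egg collections after pre-laying periods, L3 larvae were staged by the colour left in the gut, and pupae were aged from the white prepupa (WPP). The 24 embryo samples were barcoded in 1 multiplexed library, the larvae and pupae in another, and the adults in the third, so that embryos, larvae with pupae, and adults differ in library as well as in stage. Adult RNA was also extracted with another reagent and sequenced on another instrument. No test was made across these 3 multiplexed libraries.

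The authors deposited start-site signal per gene in RPM (reads per 1000000 reads) for 12698 genes, with a gene's peaks given as a single value. Each column summed to 1000000.0 RPM, so the values are shares of the reads in genic peaks. The submitters' processing notes name the genome build dm3 and the programs STAR and Cufflinks, without a version or a role. How reads were counted, and whether duplicate reads were removed, is not given in the sources used here. Within a tolerance of 0.01 of a read, 100.0% of the values in every library were whole multiples of the smallest value above 0, and whole reads were recovered from that step. For the 16 to 17 h library the step lies close to a round decimal fraction, so its recovered reads are less certain. Recovered reads came to 180571631, with 698702 to 16690598 per library.

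A further table that the authors deposited, also in RPM, covered 186 transposon classes annotated by RepeatMasker. Its columns summed to between 940338 and 1001732, so its values are shares of transposon reads and not of the whole library. How reads that match several copies were shared out is not given in the sources used here. Its 3 L3 columns carry the same heading, so the 3 L3 stages could not be told apart there, and they entered as larval libraries without a stage. Peaks of the whole series were deposited as a list of 31080 peaks and a list of 24264 peaks attributed to genes, each with a score whose meaning is not given in the sources used here. Coverage tracks of the pooled series were not used here.

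In all 5 pupal columns of the gene table, genes of the minus strand were listed at 0. Larvae and pupae were therefore compared on plus-strand genes alone, with each library rescaled to values per 1000000 plus-strand reads. Whether the pupal transposon values also come from 1 strand cannot be told from the table.

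Gene identifiers were matched to symbols for 12088 of 12698 genes by gene identifier, locus tag or synonym, and 610 stayed without a symbol. Positions are those of a gene's peak with the highest score, on dm3, taken from the peak list with starts counted from 1. A reference annotation of a later build was used for symbols and not for positions. Genes whose symbol is only a CG or CR number were counted and not named, unless a list holds them or they were the highest gene of a pupal library.

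Embryo libraries were placed in 6 groups of 4 consecutive hours. Values were taken as log2(RPM + 1), genes with at least 2 RPM in at least 3 libraries were kept, and groups were compared with limma 3.58.1 (lmFit, eBayes with a trend) in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and at least a 2-fold change. The 3 embryo comparisons (4 to 8 h against 0 to 4 h, 12 to 16 h against 4 to 8 h, 20 to 24 h against 12 to 16 h) shared 1 fit of the 24 libraries with 18 residual degrees of freedom. The comparison of pupae with larvae had 5 libraries a side and 8 residual degrees of freedom. Libraries of a group are neighbouring stages and not replicates, so the SD and SE include change within the group and the tests weigh a difference against it. Courses over the 24 embryo hours were tested with a limma F test of a natural spline with 5 degrees of freedom. Transposon classes were tested in the same way with the same settings, with a larger added constant and a higher minimum among the alternatives.

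The 25 gene lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. The lists cover maternal mRNAs, early zygotic patterning and cellularisation genes, Hox and segment polarity genes, DNA replication and the cell cycle, ribosomal proteins, proteasome subunits, neuronal genes, muscle genes, cuticle proteins, tanning and pigment enzymes, digestive enzymes, larval serum proteins, salivary glue proteins, ecdysone response genes, phototransduction, chemosensory proteins, spermatogenesis, male accessory gland proteins, egg coat and yolk proteins, the piRNA pathway, antimicrobial and recognition proteins, blood cell and basement membrane genes, heat shock proteins, glycolysis, and detoxification enzymes. 2 genes caught by a name pattern, Cp190 and Cyp40, were left out of their lists because they belong to other families. Lists with at least 4 tested members were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Counts of called members are given over all genes and, in addition, adjusted over the list alone.

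For each tested comparison, the genes named were the 6 largest rises and the 6 largest falls among called genes whose groups did not overlap and whose higher mean reached 20 RPM, and up to 3 called members with the highest mean from each list with at least 2 called members. Any other gene named was chosen after its values were seen. For a gene at 0 in every library of a group, the fold is a lower bound against a floor of 3 reads over the group.

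Adult males and females had 1 library each, so no test was possible. Genes were called at a ratio of at least 4 on RPM + 1 with at least 10 RPM in the higher sex, and exact Poisson intervals at the 95% level were computed for each sex. A list's median log2 ratio was ranked against 10000 random lists of the same size and similar mean RPM. Intervals and floors cover counting error only. A peak counted as genic when it overlapped a genic peak by at least 1 bp on the same strand.

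Alternatives were other added constants (0.25 and 4), no minimum or a minimum of 10 RPM, scaling by median-of-ratios factors, no fold threshold, a robust prior, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, only the compared groups in the fit, and each library left out in turn. A planned test of promoter switching was not run because the gene table gives 1 value per gene. The rest of the work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

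The tests were tried on simulated reads with known changes, drawn apart for each gene with a dispersion of 0.1. For the group tests, the libraries of a group had the same mean. Real groups hold stages that differ, and real list members can move together, so these rates describe the simulation and not the data. Under the settings of the first embryo comparison, 53 of 54 genes changed 4-fold, 13 of 51 changed 2-fold and 1 of 47 changed 1.5-fold were called, and 5 of 9437 unchanged genes. Under those of the pupal comparison the calls were 49 of 50 at 4-fold, 21 of 52 at 2-fold and 7 of 5441 unchanged genes. The spline test found 200 of 200 changed genes and 8 of 9418 unchanged ones. camera found the shifted list and 0 of 24 unshifted lists (preset correlation, adjusted p below 0.05).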

Results

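RAMPAGE signal at transcription start sites was measured in 36 libraries of whole animals. They comprised 24 hourly embryo windows, L1 and L2 larvae, L3 larvae with dark, light and clear guts, pupae 1 to 5 days after the white prepupa, and males and females 5 days after eclosion. Embryos were grouped into 6 periods of 4 h with 4 libraries each, and larvae and pupae into 5 libraries each. No stage had a replicate library. Recovered reads ranged from 698702 to 11856035 per embryo library, from 873086 to 14259966 in larvae and from 1066282 to 16690598 in pupae. They were 8790853 in males and 11281352 in females. Genes above 0 numbered between 7859 and 10538 per embryo library, 5520 to 9968 in larvae, 11604 in males and 9944 in females. In the 5 pupal libraries 4625 to 5495 genes were above 0, and no minus-strand gene was among them. Minus-strand genes held 48.73% to 56.6% of the signal in each of the 31 other libraries. Across genes, which are not independent replicates, neighbouring embryo hours had a Pearson correlation of log2 values between 0.944 and 0.981, and the windows at the ends of embryogenesis one of 0.632.

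**Figure D1:**
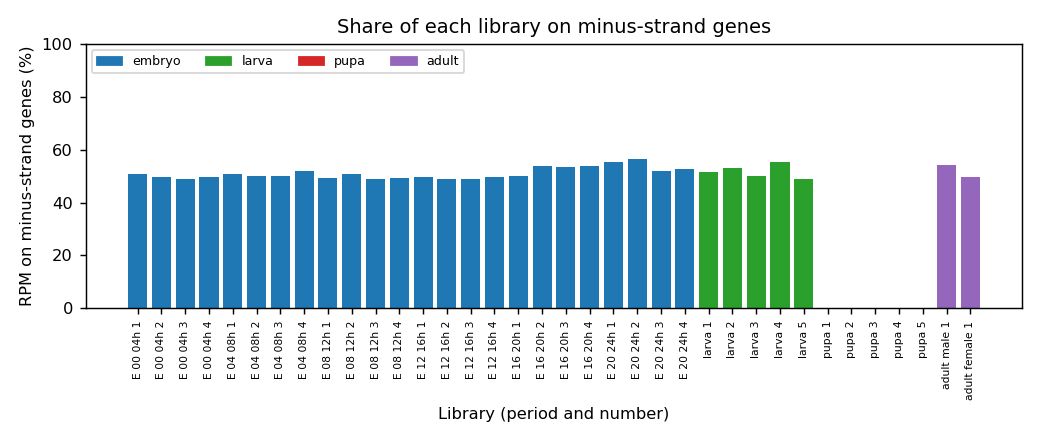
Percent of RPM on minus-strand genes in each library (bars, 1 library each, coloured by stage). Embryo, larval and adult libraries lie between 48.73% and 56.6%, and the 5 pupal libraries are at 0.

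The hourly series asked when in embryogenesis the capped RNA of each gene is most abundant, whether newly made or loaded into the egg. Maternal mRNAs, the piRNA pathway and proteasome subunits were highest at 0 to 1 h, by the summed RPM of each list. Early zygotic genes followed at 2 to 3 h, Hox and segment polarity genes at 7 to 8 h and ecdysone response genes at 13 to 14 h. Neuronal and cuticle genes were highest at 17 to 18 h, muscle genes at 19 to 20 h and digestive enzymes at 23 to 24 h. By the median of members, the highest hour was 1 to 2 h for maternal mRNAs and 6 to 7 h for Hox and segment polarity genes. It was 10 to 11 h for ecdysone response, 16 to 17 h for cuticle and 19 to 20 h for neuronal genes, and the same as by the sum for the other lists named so far. The maternal sum was 8846 RPM at its highest hour, the early zygotic sum 6905 RPM, the cuticle sum 117300 RPM, the muscle sum 52740 RPM and the digestive sum 24810 RPM. Ribosomal protein genes summed to 126300 RPM at 4 to 5 h and to 54440 RPM at 17 to 18 h. A limma F test called a course over hours for 8926 of 9940 genes. Of those, 2917 (32.7%) had their highest library in 0 to 4 h, 1391 (15.6%) in 4 to 8 h and 853 (9.6%) in 8 to 12 h. A further 1407 (15.8%) were highest in 12 to 16 h, 941 (10.5%) in 16 to 20 h and 1417 (15.9%) in 20 to 24 h.

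Genes with a short period of high signal marked each of these periods. dhd, a thioredoxin of the female germ line, was highest at 0 to 1 h (2824 RPM), halo, a regulator of lipid droplet transport, at 2 to 3 h (5033 RPM), and Nrt, the cell adhesion protein neurotactin, at 3 to 4 h (2870 RPM). The Notch pathway genes E(spl)m5-HLH and E(spl)mdelta-HLH were highest at 5 to 6 h (2215 and 1905 RPM) and Brd at 7 to 8 h (2518 RPM). nerfin-1, a zinc finger protein of neural precursors, was highest at 8 to 9 h (784 RPM), the nuclear receptor gene Hr3 at 10 to 11 h (693 RPM) and tal-1A, which encodes small peptides, at 11 to 12 h. The cuticle and chitin-binding genes ect, Gasp and TwdlF were highest between 13 and 16 h, with 22280 RPM for TwdlF at 15 to 16 h. Cpr65Ea (36730 RPM) and Cpr51A (11300 RPM) were highest at 16 to 17 h and Lcp65Ag3 at 19 to 20 h (28520 RPM), all 3 of them structural cuticle genes. Cpr78Cc was highest at 20 to 21 h (10710 RPM), and the digestive protease genes Jon99Fi and Jon25Bi at 22 to 23 h (5112 RPM) and 23 to 24 h (11020 RPM).

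**Figure D2:**
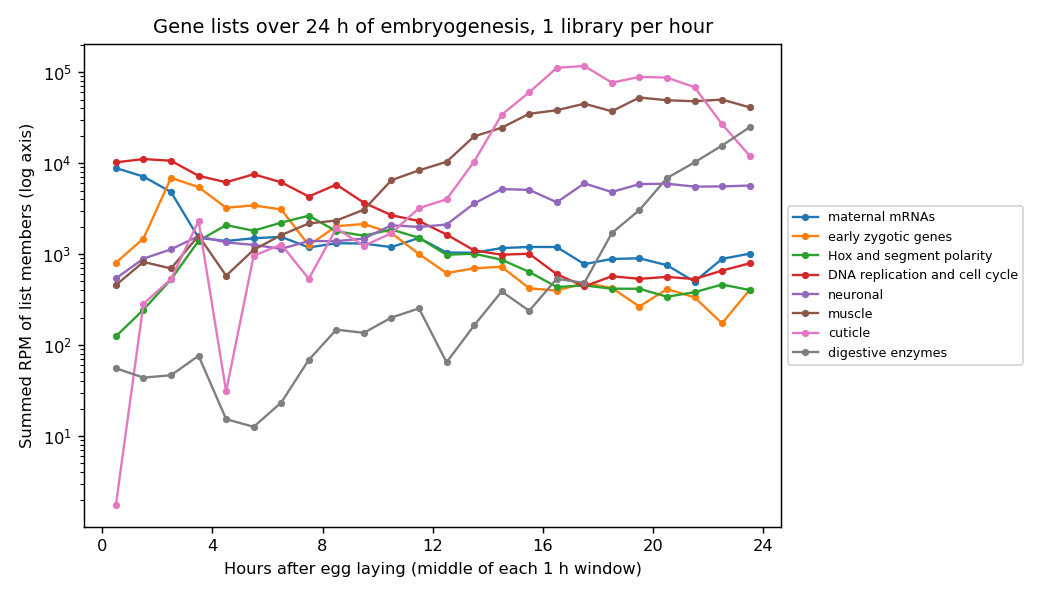
Summed RPM of 8 gene lists (log axis) against hours after egg laying, with 1 library per point. The maternal list is highest at 0 to 1 h (8846 RPM), the early zygotic list at 2 to 3 h (6905 RPM), the cuticle list at 17 to 18 h (117300 RPM) and the digestive list at 23 to 24 h (24810 RPM), and the cuticle list also reaches 2319 RPM at 3 to 4 h against 30.96 RPM at 4 to 5 h.

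Between 0 to 4 h and 4 to 8 h, mRNAs loaded into the egg fell and Hox and segment polarity genes rose, in a comparison that addresses the handover from maternal to embryonic mRNA. The values are RNA abundance and do not separate new transcription from decay. Of 17 maternal mRNAs 13 fell and the other 4 did not pass, and of 16 Hox and segment polarity genes 14 rose. osk, which assembles the germ plasm at the posterior pole, went from 532 ± 513 RPM to 10.7 ± 4.26 RPM (SD, n = 4 libraries each; log2 change -4.53 ± 0.77 SE, adjusted p = 0.000244; CG10901, dm3 chromosome 3R, 4760767 to 4760946). Ubx, the Hox gene of the posterior thorax, went from 37.3 ± 34.2 to 308 ± 84.6 RPM (log2 change 3.41 ± 0.43 SE, adjusted p = 1.65e-05; CG10388, chromosome 3R, 12560081 to 12560214). In all, limma called 1772 of 9940 genes, 924 higher and 848 lower at 4 to 8 h, with 2896 at an unadjusted p below 0.05. The libraries of the 2 groups did not overlap for 15.2% of genes, where chance gives 2.86% for libraries in random order. Libraries of a group are neighbouring stages, so the chance shares given here and below are a guide and not a test.

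The maternal list was tested with camera at an adjusted p = 1.98e-10, but its adjusted p = 0.126 with an estimated correlation. Besides osk, it includes gnu (928 ± 865 to 26.7 ± 15.3 RPM), needed for the early nuclear divisions, and smg (1634 ± 754 to 422 ± 77.1 RPM), a regulator of maternal mRNA decay. piRNA pathway genes fell in 12 of 16 cases (12 adjusted over the list alone; adjusted p = 5.77e-10, and 0.0199 with an estimated correlation). The helicase gene armi went from 500 ± 423 to 9.84 ± 4.52 RPM, spn-E from 75.99 ± 41.0 to 7.64 ± 5.74 RPM, and AGO3 from 856 ± 245 to 292 ± 58.2 RPM. This was the call that held with an estimated correlation. Glycolysis genes fell in 8 of 12 cases (8 adjusted over the list alone; adjusted p = 3.28e-06, but adjusted p = 0.149 with an estimated correlation). Hex-A, hexokinase, went from 265 ± 160 to 29.3 ± 10.3 RPM and Pglym78, phosphoglycerate mutase, from 237 ± 171 to 15.3 ± 11.8 RPM. Proteasome genes fell in 9 of 31 cases (9 adjusted over the list alone; adjusted p = 6.22e-06, but adjusted p = 0.126 with an estimated correlation), Prosalpha4 among them (538 ± 146 to 118 ± 33.4 RPM). Of the 9, the calls of Prosbeta3 and Prosbeta7 were lost after median-of-ratios scaling.

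Hox and segment polarity genes (14 of 16 adjusted over the list alone; adjusted p = 7.32e-12, but adjusted p = 0.0808 with an estimated correlation) included Antp (78.0 ± 112 to 195 ± 38.9 RPM) and the Hedgehog receptor gene ptc (239 ± 199 to 747 ± 329 RPM). Blood cell and basement membrane genes rose in 8 of 14 cases (8 adjusted over the list alone; adjusted p = 0.000133, but adjusted p = 0.126 with an estimated correlation). They included the laminin chains LanB1 (123 ± 117 to 674 ± 290 RPM) and LanB2 (64.6 ± 75.7 to 355 ± 129 RPM) and srp, a GATA factor of blood and fat body (115 ± 153 to 230 ± 68.1 RPM). The early zygotic list moved both ways: 10 of 29 fell and 3 rose (11 and 3 adjusted over the list alone; adjusted p = 0.00871, but adjusted p = 0.743 with an estimated correlation). The cellularisation gene bnk had the largest fall named in this comparison, from 754 ± 1001 to 2.55 ± 1.98 RPM (log2 change -7.07 ± 0.60 SE, adjusted p = 8.57e-08; CG1480, chromosome 3R, 27019068 to 27019097). The mitotic inhibitor gene Z600 fell from 320 ± 347 to 1.29 ± 1.87 RPM. The 3 that rose were the pair-rule gene slp1 (203 ± 245 to 538 ± 261 RPM) and, chosen after their values were seen, dpp and rho. Heat shock genes fell in 7 of 16 cases and rose in 1, Hsp67Bc, chosen after its values were seen (7 and 1 adjusted over the list alone; adjusted p = 0.0177, but adjusted p = 0.343 with an estimated correlation). Hsp26 went from 1035 ± 1089 to 13.3 ± 9.83 RPM and Hsp27 from 1413 ± 1037 to 86.3 ± 24.0 RPM.

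The remaining lists were not called between 0 to 4 h and 4 to 8 h. Detoxification genes fell in 10 and rose in 5 of 61 cases (10 and 5 adjusted over the list alone), with Cyp6v1 going from 283 ± 176 to 36.6 ± 9.11 RPM. Of 16 ecdysone response genes, ImpL2, Eip63F-1 and ImpE1 rose and usp, ftz-f1 and E23 fell (4 and 3 adjusted over the list alone). The spermatogenesis list had bol, Pif1A and mia up and twe and gdl down among 5 members (3 and 2 adjusted over the list alone). twe encodes the meiotic Cdc25 phosphatase and is also supplied to the egg. Called members elsewhere were Obp99a and Ir40a of 31 chemosensory genes (1 adjusted over the list alone; the call of Ir40a was lost after scaling), Cpr49Ac and Cpr78E of 89 cuticle genes (0), Act87E and Msp300 of 21 muscle genes (2) and amd of 16 pigment genes (0; not called after scaling), all up. Called lower were Mal-A5 and Mal-B2 of 35 digestive genes (2; Mal-B2 was not tested after scaling), CycA of 26 replication genes (1), RpS5b of 78 ribosomal genes (0) and rdgB of 6 phototransduction genes (1; not called after scaling). For the replication list the median log2 change was 0.08 and the mean -0.09, with a downward test. Of the 20 neuronal genes Cadps rose and unc-13 fell (1 and 1 adjusted over the list alone). None of 7 antimicrobial genes was called by limma (0 adjusted over the list alone). For the cuticle list, summed RPM was 1.75 at 0 to 1 h, 2319 at 3 to 4 h and 30.96 at 4 to 5 h. Accessory gland, egg coat and yolk, glue and serum lists had 1 or 2 tested members each, none called.

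Among single genes, the largest rises at 4 to 8 h included the Notch targets E(spl)m7-HLH (45.96 ± 32.3 to 590 ± 136 RPM) and E(spl)mgamma-HLH (108 ± 89.5 to 1046 ± 310 RPM). They also included pip, a sulfotransferase gene (4.604 ± 2.09 to 107 ± 98.3 RPM), sing, needed for myoblast fusion (3.45 ± 3.12 to 71.9 ± 50.2 RPM), org-1, a T-box factor (3.71 ± 2.64 to 65.7 ± 64.0 RPM) and Galt, of galactose metabolism. The largest falls, besides bnk and Z600, were those of Jabba, a lipid droplet protein that anchors histones (350 ± 368 to 0.469 ± 0.544 RPM), BicC, an RNA-binding protein of oogenesis (482 ± 543 to 0.667 ± 0.784 RPM), CtsK1 and dhd (1324 ± 1440 to 8.22 ± 6.40 RPM). The count of 1772 genes was 1146 without 0 to 1 h and 830 with only the 8 compared libraries fitted. It was 2354 without the 3 to 4 h library, in which late cuticle transcripts were present, and there more genes were lower (1213) than higher (1141).

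Between 4 to 8 h and 12 to 16 h, neuronal, muscle and cuticle genes rose and DNA replication genes fell, in a comparison that covers the start of tissue differentiation. Of 20 neuronal genes 18 rose, of 21 muscle genes 18 rose, of 89 cuticle genes 66 rose, and of 26 replication and cell cycle genes 24 fell. brp, a protein of the presynaptic active zone, went from 17.4 ± 15.1 to 647 ± 365 RPM (SD, n = 4 each; log2 change 5.57 ± 0.80 SE, adjusted p = 5.25e-06; FBgn0259246, chromosome 2R, 5391216 to 5391308). CycE, the cyclin of S phase entry, went from 855 ± 240 to 88.3 ± 50.9 RPM (log2 change -3.37 ± 0.41 SE, adjusted p = 7.1e-07; CG3938, chromosome 2L, 15731757 to 15731867). limma called 4380 of 9940 genes, 2811 higher and 1569 lower, and the groups did not overlap for 40.2% of genes, where chance gives 2.86%. The median log2 change of all genes was 0.18, and 0.32 after median-of-ratios scaling.

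Replication and cell cycle genes (26 down adjusted over the list alone; camera adjusted p = 8.27e-14) gave the call that held with an estimated correlation (adjusted p = 0.036). CycA went from 1916 ± 772 to 524 ± 203 RPM and stg, the mitotic Cdc25 phosphatase, from 484 ± 184 to 92.3 ± 34.1 RPM. Neuronal genes (18 up adjusted over the list alone; adjusted p = 2.29e-09, but adjusted p = 0.195 with an estimated correlation) included the synaptic vesicle genes nSyb (9.38 ± 6.01 to 506 ± 251 RPM) and cpx (17.7 ± 19.8 to 477 ± 194 RPM). Cuticle genes (67 up adjusted over the list alone; adjusted p = 8.71e-09, but adjusted p = 0.319 with an estimated correlation) included the structural genes TwdlF (99.9 ± 105 to 9728 ± 9937 RPM), Cpr65Ea (98.4 ± 83.9 to 4078 ± 4234 RPM) and Lcp65Ag2 (102 ± 124 to 1584 ± 1003 RPM). Muscle genes (18 up adjusted over the list alone; adjusted p = 6.01e-07, but adjusted p = 0.319 with an estimated correlation) included Mlc1, a myosin light chain (187 ± 251 to 3792 ± 1207 RPM), Act57B (102 ± 105 to 4146 ± 4265 RPM) and TpnC73F, a troponin C (200 ± 250 to 2902 ± 1448 RPM).

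Glycolysis genes rose in 10 of 12 cases (10 adjusted over the list alone; adjusted p = 0.000492, but adjusted p = 0.319 with an estimated correlation), with Ald1, aldolase, going from 84.1 ± 21.1 to 781 ± 239 RPM. Tanning and pigment enzymes rose in 13 of 16 cases, and cn fell, chosen after its values were seen (13 and 1 adjusted over the list alone; adjusted p = 0.00184, but adjusted p = 0.195 with an estimated correlation). ple, tyrosine hydroxylase, went from 8.75 ± 5.33 to 553 ± 347 RPM. Ecdysone response genes rose in 8 of 16 cases (8 adjusted over the list alone; adjusted p = 0.0294, but 0.319 with an estimated correlation), with ImpE2 going from 120 ± 42.4 to 3475 ± 2473 RPM. Blood cell and basement membrane genes rose in 8 of 14 cases and srp fell (8 and 1 adjusted over the list alone; adjusted p = 0.0438, but adjusted p = 0.36 with an estimated correlation, and 0.0566 after median-of-ratios scaling, where the call of srp was lost too). The collagen IV genes Col4a1 (4.72 ± 4.76 to 169 ± 99.9 RPM) and vkg (2.31 ± 1.81 to 120 ± 57.6 RPM) were among them. Detoxification genes rose in 25 of 61 cases and GstO1 fell (25 and 1 adjusted over the list alone; adjusted p = 0.00811, but 0.36 with an estimated correlation). Chemosensory genes rose in 15 of 31 cases and Or22a fell (15 and 2 adjusted over the list alone; adjusted p = 0.0282, but 0.362 with an estimated correlation, and 0.0566 after scaling). Obp28a went from 6.40 ± 6.87 to 161 ± 59.8 RPM. GstO1 and Or22a were chosen after their values were seen. Digestive enzymes rose in 11 of 35 cases (10 adjusted over the list alone; adjusted p = 0.0448, but 0.587 with an estimated correlation, and 0.0736 after scaling).

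Proteasome genes fell in 15 of 31 cases (15 adjusted over the list alone, 10 after scaling; adjusted p = 1.67e-06, but 0.193 with an estimated correlation), Rpt2 among them (167 ± 52.6 to 62.1 ± 24.0 RPM). Early zygotic genes fell in 12 of 29 cases (11 adjusted over the list alone; adjusted p = 1.17e-05, but 0.36 with an estimated correlation), with the gap gene hb going from 131 ± 81.1 to 11.2 ± 7.12 RPM. The call of sog was lost after scaling. Hox and segment polarity genes fell in 8 of 16 cases (8 adjusted over the list alone, 6 after scaling; adjusted p = 0.00396, but 0.36 with an estimated correlation), with en, engrailed, going from 196 ± 81.3 to 21.8 ± 6.52 RPM and Ubx from 308 ± 84.6 to 102 ± 25.9 RPM. Not called were maternal mRNAs (CycB, pgc, Tl and gnu down of 17; 4 adjusted over the list alone; adjusted p = 0.051), and the piRNA pathway (tej, mael, rhi and vret down of 16; 3 adjusted over the list alone, 2 up and 3 down after scaling). Nor were antimicrobial genes (TotE, PGRP-SD and IM33 up of 7; 3) and phototransduction genes (rdgA, rdgB and rdgC:CG13814 up and Rh4 down of 6; 3 and 1; 3 and 0 after scaling). The same held for spermatogenesis (bol and Pif1A up and mia down of 5; 2 and 1) and heat shock genes (Hsp67Bc, Hsp60A and Hsc70-3 up of 16; 3). For the heat shock list the median log2 change was -0.12 and the mean 0.24, with a downward camera test. Of 78 ribosomal genes 1 rose and 5 fell (0 adjusted over the list alone). The list's median log2 change was -0.04 and turned to 0.16 after scaling, where 3 fell, without RpL31. pgc, vret and Rh4 were chosen after their values were seen. The accessory gland, egg coat and yolk, glue and serum lists, with 1 or 2 tested members each, had none called.

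The largest single rises at 12 to 16 h were those of Osi7 (23.0 ± 29.5 to 1763 ± 1323 RPM), slbo, a C/EBP transcription factor (9.39 ± 6.22 to 1035 ± 507 RPM), TwdlF and Cpr64Ad (11.3 ± 14.0 to 939 ± 770 RPM). Next were ect (69.5 ± 64.6 to 4848 ± 1983 RPM) and dyl, which shapes apical extensions of epidermal cells (52.5 ± 70.1 to 2702 ± 1360 RPM). The largest falls were those of Brd (1558 ± 667 to 5.20 ± 3.21 RPM; log2 change -8.09 ± 0.83 SE, adjusted p = 1.01e-07; CG3096, chromosome 3L, 14965560 to 14965784), of the Bearded family of Notch modulators, and the proneural genes ac (433 ± 119 to 1.45 ± 2.03 RPM) and l(1)sc (249 ± 165 to 0.864 ± 0.861 RPM). Next were BobA, of the same family as Brd, E(spl)m5-HLH (1088 ± 881 to 8.80 ± 6.34 RPM), and halo.

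Between 12 to 16 h and 20 to 24 h, digestive enzymes rose, in a comparison that covers the end of embryogenesis and hatching. Of 35 digestive enzymes 32 rose (32 adjusted over the list alone). Of 16 ecdysone response genes 6 fell and 10 did not pass (8 down adjusted over the list alone; adjusted p = 0.0164, but adjusted p = 0.293 with an estimated correlation). Jon25Bi, a serine protease of the gut, went from 29.8 ± 31.5 to 4041 ± 4698 RPM (SD, n = 4 each; log2 change 6.87 ± 0.83 SE, adjusted p = 7.89e-07; CG8867, chromosome 2L, 4955078 to 4955163). ImpE2 went from 3475 ± 2473 to 4.90 ± 1.15 RPM (log2 change -8.80 ± 0.84 SE, adjusted p = 7.45e-08; FBgn0001254, chromosome 3L, 3512595 to 3512744). limma called 2927 of 9940 genes, 1253 higher and 1674 lower, and the split turned to 1809 higher and 866 lower after median-of-ratios scaling. The median log2 change of all genes was -0.36, and 0.10 after that scaling. The groups did not overlap for 32.5% of genes, where chance gives 2.86%.

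The digestive call held with an estimated correlation (adjusted p = 2.52e-28, and 0.046 with an estimated correlation). Jon99Fi went from 28.98 ± 27.3 to 2793 ± 1894 RPM and Jon99Fii from 26.8 ± 24.5 to 2131 ± 1035 RPM. Detoxification genes rose in 27 of 61 cases, and Cyp49a1, Cyp6t1 and Cyp4e1 fell (29 and 4 adjusted over the list alone; adjusted p = 8.14e-07, but adjusted p = 0.264 with an estimated correlation). Cyp12a4 went from 1.67 ± 0.677 to 138 ± 59.2 RPM. Chemosensory genes rose in 14 of 31 cases, and Obp99a, Obp99b and Obp83ef fell (15 and 6 adjusted over the list alone; adjusted p = 0.000447, but adjusted p = 0.318 with an estimated correlation). Obp56d went from 37.8 ± 20.2 to 631 ± 110 RPM. Muscle genes rose in 4 of 21 cases, TpnC25D, Zasp66, Mf and bt (3 adjusted over the list alone; adjusted p = 0.00575, but adjusted p = 0.686 with an estimated correlation). Zasp66, a Z-disc protein, went from 96.9 ± 38.5 to 3533 ± 648 RPM. Antimicrobial and recognition genes moved both ways, with PGRP-SC1a, PGRP-SC2, PGRP-SB1 and IM33 up and TotE and PGRP-SD down of 7 (5 and 2 adjusted over the list alone; adjusted p = 0.0275, but adjusted p = 0.318 with an estimated correlation, and 0.0815 after scaling). Of the 20 neuronal genes Rdl and Rim rose (1 adjusted over the list alone; adjusted p = 0.0275, but adjusted p = 0.699 with an estimated correlation), and of the 12 glycolysis genes Hex-A and PyK (2 adjusted over the list alone; adjusted p = 0.0275, but adjusted p = 0.686 with an estimated correlation). The genes of this paragraph without a value were chosen after their values were seen, except Obp99a, bt, Mf, Rdl, Rim, Hex-A, PyK, PGRP-SC2, IM33 and TotE.

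Cuticle genes split, with 29 up and 22 down of 89 (30 and 24 adjusted over the list alone; adjusted p = 0.0205, but adjusted p = 0.812 with an estimated correlation, and 0.314 after scaling). Lcp65Ag3 went from 808 ± 591 to 16200 ± 10480 RPM, TwdlF from 9728 ± 9937 to 20.1 ± 19.8 RPM, and Cpr65Ea from 4078 ± 4234 to 155 ± 128 RPM, a call lost after scaling. Of the ecdysone response genes, ImpL1 went from 1285 ± 1143 to 1.84 ± 1.35 RPM and ImpE1 from 519 ± 310 to 7.75 ± 2.18 RPM. Replication genes fell in 6 of 26 cases (4 adjusted over the list alone; adjusted p = 0.0306, but 0.686 with an estimated correlation), among them stg (92.3 ± 34.1 to 17.1 ± 4.41 RPM), CycE and Cdc6. After scaling 3 fell, without Cdc6. Hox and segment polarity genes fell in 5 of 16 cases, ptc, wg, Scr, slp2 and inv (6 adjusted over the list alone; adjusted p = 0.0378, but adjusted p = 0.699 with an estimated correlation). Only ptc was called after scaling. The proteasome genes Rpn12, Rpt4 and Prosalpha5 fell, of 31 (3 adjusted over the list alone; adjusted p = 0.0358, but adjusted p = 0.686 with an estimated correlation, and 0.0815 after scaling, where all 3 calls were lost).

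Other lists were not called between 12 to 16 h and 20 to 24 h. Blood cell and basement membrane genes went down in 7 of 14 cases and He, Hml and NimC1, markers of blood cells, went up (7 and 3 adjusted over the list alone), with LanB1 falling from 1157 ± 358 to 194 ± 25.7 RPM. After scaling 4 fell, not including LanB2 or Ppn. Of 16 pigment genes Ddc rose and amd, bw, w and yellow-d2 fell (1 and 4 adjusted over the list alone; 2 and 2 after scaling, w not called), and amd, a homologue of Ddc that acts in cuticle formation, went from 77.1 ± 40.03 to 0.828 ± 0.944 RPM. Of 16 heat shock genes Hsp68 and Hsc70-1 rose and Hsc70-3 and Hsp67Bc fell (2 and 2 adjusted over the list alone), and the call of Hsp67Bc was lost after scaling. The list's median log2 change was -0.08, its mean 0.17 and its camera test upward, and the median turned to 0.30 after scaling. Ribosomal genes had a median log2 change of -0.36, which turned to 0.17 after scaling, with RpL38 and RpS5b called lower of 78 (2 adjusted over the list alone; the call of RpL38 was lost after scaling). The early zygotic genes run and slp1 fell of 29 (0 adjusted over the list alone) and the maternal gene gcl of 17 (0), all calls being lost after scaling. Rh5 rose of 6 phototransduction genes (1), with a median log2 change of -0.03 that turned to 0.46 after scaling. The piRNA list of 16 and the spermatogenesis list of 5 had 0 called genes by limma (0 adjusted over the list alone). For the piRNA list the median log2 change was 0.10 and the mean -0.05, with an upward camera test. Single-member lists had Sgs8 (glue) up and Lsp1gamma (serum, not tested after scaling) down, and none of 2 accessory gland and 2 egg coat and yolk genes was called. He, Hml, NimC1, bw, yellow-d2, Hsc70-1, gcl, Rh5, Sgs8, Lsp1gamma, slp2 and inv were chosen after their values were seen.

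The largest single rises at 20 to 24 h were those of Pig1, a salivary gland gene (2.98 ± 3.18 to 601 ± 470 RPM), 4 Jonah proteases, Jon25Bi, Jon25Bii (6.25 ± 8.91 to 540 ± 271 RPM), Jon99Fii and Jon99Fi, and BomS3, an immune peptide gene (9.02 ± 9.51 to 680 ± 118 RPM). The largest falls were those of nur (11450 ± 4107 to 21.4 ± 19.4 RPM; log2 change -9.50 ± 1.17 SE, adjusted p = 9.83e-07; CG31813, chromosome 2L, 13736117 to 13736220). They were followed by Osi7 (1763 ± 1323 to 2.03 ± 1.302 RPM), ImpE2, Osi6 (2015 ± 1718 to 3.21 ± 1.43 RPM), TwdlF and slbo (1035 ± 507 to 2.42 ± 1.93 RPM). The count of called lists, 12, was 6 without 12 to 13 h and 7 without 20 to 21 h.

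Between larvae and pupae, digestive enzymes were lower as a list among plus-strand genes, in a comparison that covers metamorphosis. Of 17 digestive enzymes 8 fell and 9 did not pass (11 down adjusted over the list alone; adjusted p = 4.36e-15, and 0.0396 with an estimated correlation). Of 16 spermatogenesis genes 4 rose and 12 did not pass (16 up adjusted over the list alone; adjusted p = 4.62e-08, but adjusted p = 0.425 with an estimated correlation). Of the 4, the call of dj was lost after median-of-ratios scaling. Jon99Fi went from 8983 ± 4496 to 346 ± 751 in RPM of the plus-strand reads (SD, n = 5 each; log2 change -9.04 ± 1.43 SE, adjusted p = 0.00614; CG18030, chromosome 3R, 26314665 to 26314703). tHMG2, an HMG-box gene of the male germ line, went from 54.4 ± 94.5 to 668 ± 582 (log2 change 6.05 ± 1.37 SE, adjusted p = 0.0253; FBgn0038979, chromosome 3R, 18318794 to 18318904). limma called 162 of 5404 plus-strand genes, 80 higher and 82 lower in pupae, with 1162 at an unadjusted p below 0.05, and the groups did not overlap for 2.9% of genes, where chance gives 0.79%. The median log2 change of all tested genes was 0.62, and 0.45 after median-of-ratios scaling. edgeR called 0 genes (779 at an unadjusted p below 0.05, smallest adjusted p 0.0594) and DESeq2 440. The limma count was 607 (418 higher and 189 lower) without the L3 clear gut larvae, 366 (231 and 135) without the pupae of 1 day and 240 (163 and 77) without those of 5 days. Leaving out any other larva gave 42 to 59 and any other pupa 33 to 45, each with more genes lower than higher. The splits ran from 24 and 35 without L3 light gut larvae to 5 and 28 without the pupae of 3 days and 6 and 35 without those of 4 days. Without CG17298, the highest gene of pupae of 5 days, an alternative chosen after its values were seen, the count was 222, 141 higher and 81 lower.

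Called members of the digestive list, the list whose call held with an estimated correlation, included Jon66Ci (4487 ± 6612 to 227 ± 504) and Jon65Aiv (2207 ± 1489 to 63.3 ± 128). Spermatogenesis genes included Mst84Da, a sperm tail gene (27.97 ± 51.5 to 394 ± 309). S-Lap8, a sperm leucyl aminopeptidase gene, was at 0 in all 5 larval libraries and at least 259-fold higher in pupae. The fourth was dj (19.1 ± 39.0 to 244 ± 219). Cuticle genes fell in 5 of 50 cases, Lcp4, Cpr67Fa1, Cpr67Fa2, Lcp65Ac and Cpr47Eb, and Cpr47Ee rose (12 and 5 adjusted over the list alone; adjusted p = 2.83e-05, but adjusted p = 0.425 with an estimated correlation). Lcp4 went from 35260 ± 45320 to 1705 ± 3764 and Cpr67Fa1 from 10180 ± 12150 to 109 ± 188. Of 36 detoxification genes Cyp12a4 (352 ± 143 to 34.1 ± 48.4), Cyp6d5 (84.1 ± 44.6 to 5.96 ± 6.13) and Cyp4ac1 (53.4 ± 33.6 to 1.17 ± 1.76) fell (3 adjusted over the list alone; adjusted p = 5.4e-05, but adjusted p = 0.362 with an estimated correlation).

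Further lists were called between larvae and pupae without a called member over all genes. They were ribosomal proteins (36 members; adjusted p = 4.11e-06, but adjusted p = 0.563 with an estimated correlation), glue proteins (7; adjusted p = 0.000132, but adjusted p = 0.425 with an estimated correlation) and glycolysis (5; adjusted p = 0.0286, but adjusted p = 0.491 with an estimated correlation), with a downward test and 0 members adjusted over the list alone. Phototransduction genes had an upward test (7 members, 5 up adjusted over the list alone; adjusted p = 0.00912, but adjusted p = 0.425 with an estimated correlation). So had neuronal genes (10, 1 up adjusted over the list alone; adjusted p = 0.0237, but adjusted p = 0.563 with an estimated correlation) and heat shock genes (10, 6 up adjusted over the list alone; adjusted p = 0.0286, but adjusted p = 0.563 with an estimated correlation). Median log2 changes were -0.60 for ribosomal, -4.09 for glue, 2.10 for phototransduction and 2.73 for heat shock genes, beside 0.62 for all genes. Of 12 muscle genes, not called as a list, Act79B (0.221 ± 0.362 to 2057 ± 2402) and Act88F (0.0546 ± 0.122 to 2017 ± 2050), actins of adult muscle, rose and Act57B, an actin of larval muscle, fell from 11040 ± 8019 to 1287 ± 1778 (2 and 1 adjusted over the list alone). The calls of Act88F and Act57B were lost after scaling. The muscle list's median log2 change was -0.58 and its mean 0.49, with a downward test.

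The other lists were not called in pupae. TotB rose of 20 antimicrobial genes (3 adjusted over the list alone), Obp56h fell of 11 chemosensory genes (1), with a median log2 change of 0.80 and a downward test, and Acp32CD rose of 3 accessory gland genes (1 up and 1 down adjusted over the list alone). Obp56h, Acp32CD, Lcp65Ac and Cpr47Eb were chosen after their values were seen. limma called 0 of 8 early zygotic genes (1 down adjusted over the list alone) and 0 of 6 ecdysone genes (1 down). It also called 0 of 5 blood cell, 5 Hox and segment polarity, 4 maternal, 8 pigment, 5 piRNA, 23 proteasome, 8 replication, 5 serum and 1 egg coat and yolk genes (0 adjusted over the list alone in each). The serum list had a median log2 change of -0.33 and a mean of 0.58, the blood cell list 0.56 and -0.27, and the early zygotic, ecdysone and piRNA lists positive medians (0.19, 0.64 and 0.88) with a downward test. The early zygotic median turned to -0.01 after scaling.

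**Figure D3:**
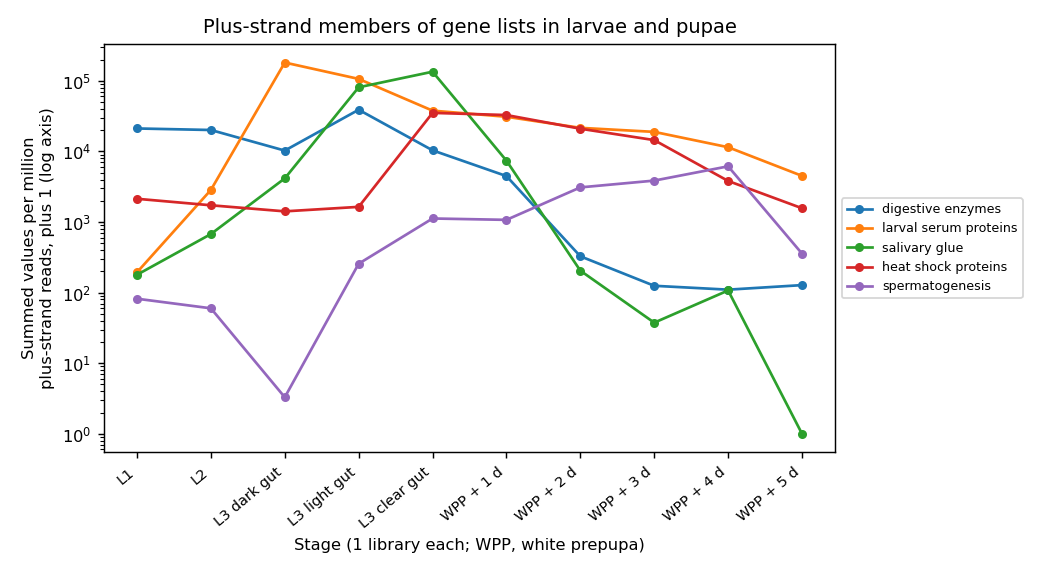
Summed values of plus-strand members of 5 gene lists in RPM of the plus-strand reads, with 1 added (log axis), in 5 larval and 5 pupal stages (1 library per point). Serum genes are highest in L3 dark gut larvae (181500), glue genes in L3 clear gut larvae (134600), and spermatogenesis genes 4 days after the white prepupa (6148).

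The other large rises in pupae were those of Jhe, juvenile hormone esterase (0 in all 5 larval libraries and 63.7 ± 48.8 in pupae, at least 370-fold higher; FBgn0010052, chromosome 2R, 12007636 to 12007649) and NimC4, a phagocytosis receptor (0 in larvae, at least 294-fold higher). TotB, a stress-induced gene (1.03 ± 2.16 to 114 ± 168), COX6AL, a cytochrome c oxidase subunit (1.60 ± 3.59 to 104 ± 91.5), and Cpr47Ee rose too. The other large falls were those of Jon65Aiii (1975 ± 1126 to 90.2 ± 198), Jon99Ciii, the trypsin gene betaTry (220 ± 119 to 8.33 ± 17.9), and Muc26B, a mucin gene (545 ± 160 to 16.2 ± 33.5).

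Transposon signal was dominated by a few classes, and their shares shifted with stage, which bears on the series' interest in transposons as a source of start sites. MDG1_I, the internal part of an LTR retrotransposon, held 68.25% of transposon reads at 0 to 1 h and 10.73% at 15 to 16 h. Its LTR entry, MDG1_LTR, averaged 956 RPM of those reads at 0 to 4 h and 1216 at 12 to 16 h. Copia_LTR held 31.15% in L2 larvae and 37.99% in pupae of 1 day. DM297_LTR held 60.23% in pupae of 4 days, against 0.91% in pupae of 2 days. Between 0 to 4 h and 4 to 8 h limma called 36 of 185 tested classes, 10 higher and 26 lower. ROO_LTR rose from 20490 ± 8947 to 60050 ± 18410 in RPM of the transposon reads (log2 change 1.62 ± 0.34 SE, adjusted p = 0.00115) and DM297_LTR from 10590 ± 5405 to 32170 ± 12960, and HETA, a telomeric retrotransposon, fell from 6383 ± 3944 to 464 ± 383. DM176_LTR, ROOA_LTR and DM1731_LTR also rose, ROVER and DIVER2_LTR fell, and BARI_DM and LOOPER1_DM, lower as well, were listed at 0 in all 4 libraries of 4 to 8 h. With a constant of 300 the calls of BARI_DM, LOOPER1_DM and DIVER2_LTR were lost and the split was 10 higher and 16 lower, and it was 12 and 16 with a minimum of 1000. The count was 23 (6 higher and 17 lower) without the 5 to 6 h library. The split was 13 higher and 14 lower without 7 to 8 h, 18 and 23 without 3 to 4 h, and 18 and 27 without 4 to 5 h.

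Between 4 to 8 h and 12 to 16 h, 47 transposon classes were higher and 7 lower of 185. After median-of-ratios scaling the calls were 23 higher, all among the 47, and 15 lower, and the median log2 change of all classes went from 1.08 to 0.04. BURDOCK_LTR rose from 418 ± 315 to 18820 ± 3564 (log2 change 5.85 ± 0.47 SE, adjusted p = 3.6e-11), and by 4.69 on the log2 scale after scaling. Gypsy6_LTR, ZAM_LTR, Transib5 and Invader6_I rose as well, from means of 41.15, 12.66, 7.731 and 73.77 at 4 to 8 h. The smallest value above 0 there was 6.09 in the 4 to 5 h library and 73.21 in the 7 to 8 h library. These means thus lie near the floor, and the size of their log2 changes depends on the added constant. HOBO, a DNA transposon, fell from 50060 ± 23570 to 4192 ± 1342 (adjusted p = 6.4e-09), BS3_DM from 5804 ± 2885 to 726 ± 421, and ROO_LTR from 60050 ± 18410 to 14090 ± 3392. Gypsy_DS and Ulysses_I were lower and listed at 0 in all 4 libraries of 12 to 16 h, and both calls were lost with a constant of 300. Between 12 to 16 h and 20 to 24 h, 8 classes were called. DM176_LTR rose from 7352 ± 807 to 22800 ± 6769, and 7 fell, among them ROVER-LTR_DM (36710 ± 3583 to 14410 ± 1788), G6_DM, ROOA_LTR, Gypsy12A_LTR and Invader6_LTR. That count was 0 by limma without 12 to 13 h, 13 to 14 h or 22 to 23 h, with 37 classes at an unadjusted p below 0.05 when all were used. It was 16 (2 higher and 14 lower) without MDG1_I, 14 (3 and 11) and 21 (10 and 11) with constants of 4 and 300 added to the values, and 11 (5 and 6) after median-of-ratios scaling. The call of Invader6_LTR was lost with the constant of 300 and that of ROVER-LTR_DM after scaling.

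In pupae against larvae 2 of 153 transposon classes were called, TABOR_LTR but not TABOR_I higher (107 ± 135 to 5299 ± 2950, n = 5 each) and R2_DM, which inserts into ribosomal DNA, lower (176600 ± 72170 to 48010 ± 15240; log2 change -1.83 ± 0.38 SE, adjusted p = 0.0397). limma called 0 without L2 or the pupae of 3, 4 or 5 days, with 23 classes at an unadjusted p below 0.05 when all were used. It also called 0 after median-of-ratios scaling, with 25 at an unadjusted p below 0.05. It called 5 without the pupae of 1 day, and 5 without an L3 library of unknown stage. In adults 53 classes differed at least 4-fold, 37 higher in males and 16 in females, and 30 and 28 after scaling. TIRANT_LTR was at 383900 RPM of the transposon reads in females (38.67%) and at 5118 in males (0.54%).

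**Figure D4:**
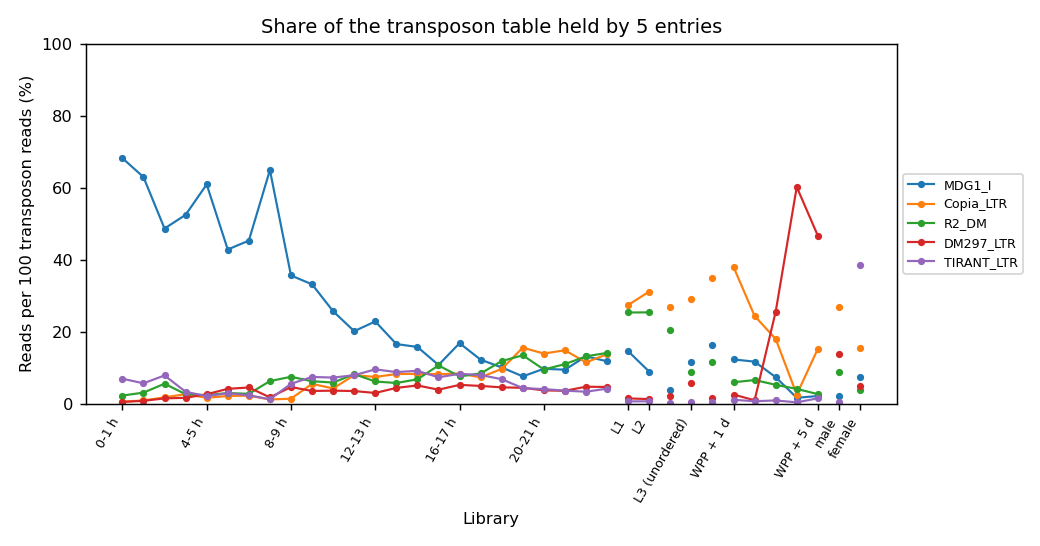
Percent of transposon reads held by 5 transposon classes in each library (points, 1 library each; the 3 L3 libraries carry no stage in this table). MDG1_I falls from 68.25% at 0 to 1 h to 10.73% at 15 to 16 h, DM297_LTR reaches 60.23% in pupae of 4 days, and TIRANT_LTR is at 38.67% in females and 0.54% in males.

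Adult males and females differed most in seminal fluid, sperm and eggshell genes. With 1 library each, the differences carry counting intervals and no test. All but 1 of 52 accessory gland genes were at least 4-fold higher in males, 29 of 36 spermatogenesis genes were higher in males and 1 in females, and all 22 egg coat and yolk genes were higher in females. Sfp60F, a seminal fluid protein gene, was at 24140 RPM in males (95% Poisson interval 24040 to 24240) and 1.33 RPM in females (0.744 to 2.19; FBgn0259968, chromosome 2R, 21060177 to 21060216). Cp15, a chorion gene, was at 13.0 RPM in males (10.7 to 15.6) and 8731 RPM in females (8676 to 8785; CG6519, chromosome 3L, 8721454 to 8721746). Of 8959 genes 2943 differed at this size, 1899 higher in males and 1044 in females (2132 and 815 after median-of-ratios scaling). The median log2 ratio of all genes, male over female, was -0.09, and 0.17 after median-of-ratios scaling.

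Among male-higher genes, Sfp87B was at 10010 RPM against 0.975, Ebp, of the ejaculatory bulb, at 4601 against 0.089, and Acp26Aa at 3530 against 0.177. Acp53C14b and Acp32CD had 0 reads in females and were at least 24620-fold and 21080-fold higher in males, as were EbpII, Sfp24Bb, Acp36DE and Mst57Dc by at least 7406-fold. The sperm genes tHMG2 and ocn had 0 reads in females and were at least 3967-fold and 3614-fold higher in males. Female-higher genes included the vitelline membrane genes Vm26Aa (15290 RPM against 30.6), Vm26Ab, Vm34Ca and Vml, the chorion genes Cp36 and Cp38, and the yolk protein genes Yp1 (3935 against 7.74) and Yp3 (7480 against 19.8). Maternal, replication and piRNA genes were also more often higher in females. Of 18 maternal mRNAs 15 were higher in females, of 26 replication genes 21 and of 16 piRNA genes 11, with none of these 3 lists higher in males. Of 80 ribosomal protein genes 8 were higher in females and 2 in males, a smaller share in each sex than over all genes. osk was at 869 RPM in females and 2.84 in males, gnu at 684 and 0.114, CycA at 2349 and 73.8, and tej at 44.2 and 2.28. The medians of the maternal, replication, piRNA and ribosomal lists ranked at percentile 0.0 among 10000 random lists of the same size and similar mean RPM.

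The medians of the muscle, neuronal, phototransduction, chemosensory and detoxification lists leaned towards males, at percentiles 100, 99.9, 99.7, 99.4 and 99.3 among random lists. Members at least 4-fold higher in males were a larger share of the phototransduction, neuronal and chemosensory lists than of all genes (1899 of 8959), and a smaller share of the muscle and detoxification lists. These shares were not tested. RPM values are shares of the reads of whole animals, and egg coat and yolk genes alone summed to 61930 RPM in females and 128.7 RPM in males. A difference in tissue make-up between the sexes was not separated from a difference in expression. Of 19 phototransduction genes 8 were higher in males and none in females, with ninaE, the main rhodopsin, at 6197 and 802 RPM. Neuronal genes were higher in males in 9 of 19 cases (cpx, 931 and 144 RPM) and muscle genes in 2 of 25 (Act79B, 315 and 65.7 RPM). Chemosensory genes were higher in males in 11 of 34 with 1 higher in females (Obp56g, 356 and 1.24 RPM), and detoxification genes in 8 of 68 with 4 higher in females (Cyp4g1, 10390 and 1929 RPM). Proteasome genes had a median log2 ratio of -0.27 and summed to 3503 RPM in males and 5113 in females, and 10 of 43 were higher in males, a share close to that of all genes. They included Prosbeta4R2, a testis-specific subunit with 0 reads in females and at least 494-fold higher in males, and Prosbeta4 alone was higher in females (539 and 79.4 RPM). Counts for the rest were 3 higher in males and 2 in females of 13 early zygotic genes, 3 and 0 of 11 Hox and segment polarity genes, 4 and 1 of 35 cuticle genes, and 2 and 0 of 13 pigment genes. They were 6 and 3 of 38 digestive genes, 0 and 1 of 14 ecdysone genes, 3 and 5 of 22 antimicrobial genes, 3 and 0 of 14 blood cell genes, and 4 and 2 of 19 heat shock genes. None of 12 glycolysis or 2 serum genes differed at this size, and no glue gene reached 10 RPM.

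**Figure D5:**
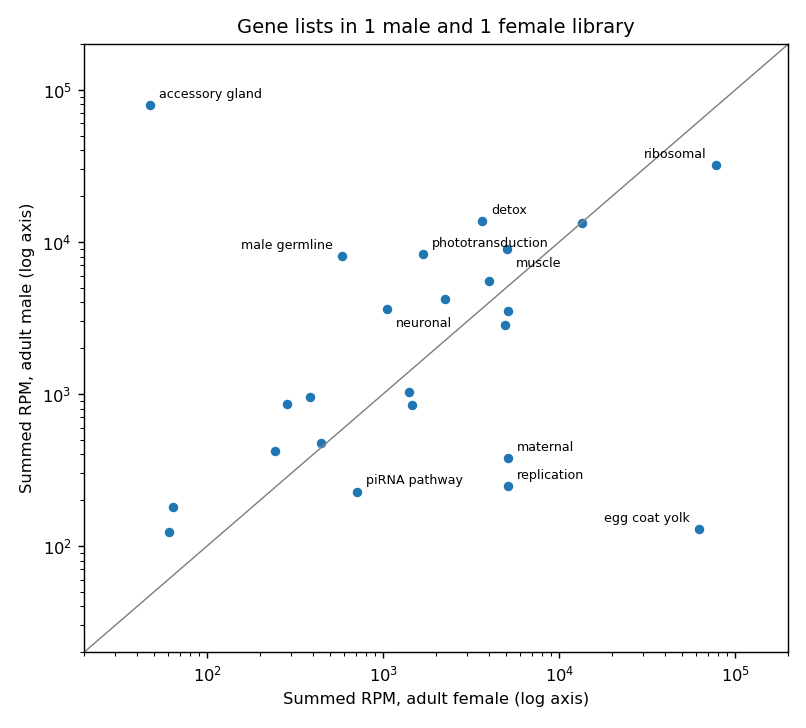
Summed RPM of gene lists in the adult male library against the adult female library (both axes log, 1 point per list, grey line for equal values). Accessory gland genes sum to 79010 RPM in males and 47.07 RPM in females, and egg coat and yolk genes to 128.7 and 61930 RPM.

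Most start-site peaks lay at annotated genes, and 40.2% of genes had more than 1 peak. Of 31080 peaks 23659 (76.12%) overlapped a genic peak on the same strand. The other 7421 had a median width of 15 bp against 53 bp for genic peaks, a median score of 32 against 289, and 5.36% of the summed score. Without an annotated gene, the highest score was 974101, at 8839532 to 8840283 on the minus strand of chromosome U, which holds unplaced sequence. Msp300, a giant muscle and nuclear envelope protein, had the most peaks of any gene, 30. In all, 5108 of 12705 genes had at least 2 peaks, among them all 12 glycolysis genes, 90.0% of the 20 neuronal genes and 3.1% of the 32 antimicrobial genes. The strongest peak of a gene had a median width of 82 bp over all genes. List medians ran from 14 bp for antimicrobial genes and 17 bp for chemosensory genes to 175 bp for ribosomal proteins and 204 bp for muscle genes.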

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

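The tests on the pupal zeros, on late transcripts at 3 to 4 h, on depth at 20 to 24 h and on other groupings of the libraries were chosen after those results were seen, and that on abundant genes at 20 to 24 h before. A library was singled out where its gap to the nearest other of its group took up most of the group's range (Dixon's criterion at the 95% level), which chance gives in about 1 of 20 groups. Of 410 values tested 40 met it, where chance gives 20.5. They comprised 5 of 31 values that describe a library and 35 of 379 gene values. Of the 25 gene values in embryos, 20 belonged to the earliest or latest hour of a group, where the libraries are neighbouring hours.

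Pupae of 5 days had the most recovered reads of the pupae (16.69 in units of 1000000 reads, nearest 4.42) and the highest share of RPM in their 10 highest genes (57.3%, nearest 25.08%). The 6 to 7 h library had 9461 genes above 0 (nearest 8269), L3 dark gut larvae 5520 (nearest 9063), and the 16 to 17 h library had 49.94% of RPM on minus-strand genes (nearest 53.26%).

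Gene values in RPM follow, with the nearest other library of the group in parentheses. At 4 to 5 h Mal-B2 was high at 2.025 (0.1679), and Hex-A at 13.89 (33.91), slbo at 0.2893 (11.04), and nSyb and ple at 0.868 (10.25 for both) were low. At 7 to 8 h Gapdh2 at 48.66 (10.41) and PGRP-SD at 1.431 (0) were high, and gnu at 4.294 (29.88), osk at 4.294 (12.62), BobA at 174.6 (299.3) and rhi at 2.862 (7.812) were low. gdl was low at 5 to 6 h, at 72.56 (124.5). Hex-A at 39.06 (287.5) and unc-13 at 31.48 (82.68) were low at 3 to 4 h, and AGO3 at 2 to 3 h, at 489.6 (960.6). At 12 to 13 h IM33 at 2.228 (10.35), Mlc1 at 1987 (4258) and Rim at 2.228 (21.1) were low. At 14 to 15 h bol was low at 182.1 (787.7) and Pig1 high at 7.747 (1.563). At 20 to 21 h Jon25Bii at 138.3 (626.6) and ImpE2 at 3.18 (5.402) were low and TotE was high at 0.3974 (0). Hsc70-3 was high at 22 to 23 h, at 105.5 (81.5), and Hsp67Bc low at 23 to 24 h, at 24.82 (37.27). The PGRP-SD, slbo and TotE values are 1 read each.

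Among larvae and pupae, in RPM of the plus-strand reads, L3 clear gut larvae were high in COX6AL at 8.02 (0), TotB at 4.882 (0.278) and Cpr47Ee at 22.32 (0), and low in Cpr67Fa1 at 41.49 (5932). L3 light gut larvae were high in Act88F at 0.273 (0). Pupae of 1 day were high in Jon99Ciii at 336.7 (3.935), betaTry at 40.33 (1.312), Lcp4 at 8437 (43.61) and Jon66Ci at 1128 (3.935), and pupae of 5 days were low in S-Lap8 at 3.835 (32.83). A signal in data outside the gene comparisons was that of 7421 peaks that overlapped no genic peak.

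Minus-strand genes were at 0 in all pupal libraries. Of 31920 minus-strand values there, 0 were above 0. Low depth is argued against by the 7 to 8 h library, which had 4114 minus-strand genes above 0 at fewer reads (698702) than any pupal library. Silence of minus-strand genes is argued against by ribosomal protein genes, of which all 43 on the minus strand were at 0, while 36 of 37 on the plus strand were above 0 in every pupal library. Pupal columns made from plus-strand reads alone stay open as an explanation, which was not tested apart from the zeros themselves. How these columns were made is not given in the sources used here.

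Late transcripts were present at 3 to 4 h: for 66 genes outside the cuticle list the median value at 3 to 4 h was 2.009% of the value at 16 to 20 h, all 66 being above 0. It was 0 at 0 to 1 h and at 4 to 5 h, and 0.39% to 0.848% in the other libraries before 8 h. Older embryos in the collection would bring such transcripts together and may be the source. An equal number of reads of the wrong barcode in every library is argued against by Lcp65Ag2, with 2 reads at 0 to 1 h, 5999 at 3 to 4 h and 0 at 4 to 5 h. Carry-over from a single late library stays open, and no biological explanation was tested.

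More genes were lower than higher at 20 to 24 h against 12 to 16 h in RPM, a direction that depended on scaling. After median-of-ratios scaling, with edgeR and with DESeq2 more genes were higher than lower. The median log2 change of all genes was -0.36 in RPM and 0.1 after median-of-ratios scaling, so the tests below concern the split in RPM alone. Without the 25 genes that reach 5000 RPM, whose share of reads went from 12.7% to 20.3%, the share of called genes that were lower went from 57.2% to 50.6%, so a larger share of reads in a few abundant genes may account for part of it and stays open. Mean depth was lower at 20 to 24 h (2.09 against 2.81 in units of 1000000 reads). Lower depth is argued against as the cause, since with the reads of all 8 libraries thinned at random to the lowest depth among them (897612 reads), 56.9% to 58% of called genes were lower in 20 thinnings. A comparison of the lowest depths, planned before, decides nothing, since the mean went the other way. The difference in stage itself stays among the open explanations.

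Other groupings of the same libraries were counted, the real one included. For genes, 1 of 35 groupings reached the real count in each embryo comparison: 1772 at 4 to 8 h (highest other 1362), 4380 at 12 to 16 h (1590) and 2927 at 20 to 24 h (13). For transposon classes it was also 1 of 35 each, with 36 (highest other 20), 54 (7) and 8 (2). The real grouping thus gave the most calls, but this cannot exclude chance. Libraries of a group are neighbouring hours, so change over time favours the real grouping over mixed ones. A share of 1 of 35 is also the smallest possible. In pupae against larvae 2 of 100 groupings reached 162 genes (highest other 554) and 3 of 100 reached 2 transposon classes (highest other 7). The grouping with 554 genes set L1, L2, L3 dark gut and L3 light gut larvae with pupae of 1 day against the rest, which points to a structure of the samples. For gene lists chance cannot be excluded at 4 to 8 h, where 18 of 35 groupings gave at least 8 lists (highest other 15), at 12 to 16 h, where 2 of 35 gave at least 14 (highest other 14), and in pupae, where 8 of 100 gave at least 10 (highest other 12). At 20 to 24 h 1 of 35 gave at least 12 (highest other 11), with the same limit as for genes.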

How the results depend on the processing

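The added constant of 300 and the minimum of 1000 for transposons, scaling within the transposon table, omission of MDG1_I and of CG17298, both strands in pupae, and lists without each library were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers that link libraries of different stages. Of 206 alternatives for counts of called genes, lists, transposons or peaks, 160 were within 1.5 times the reported count and 46 were not. The naming rule gave 206 results for single genes, where a gene named in several comparisons counts in each. For these, 3823 checks gave 3375 with the same direction and call, 448 with the direction kept and the call lost, and 0 reversed, and 131 of the 206 results never lost their call. In the pupal comparison all 25 lost it at least once. Named transposon classes lost their call in 14 of 156 checks at 4 to 8 h, 6 of 155 at 12 to 16 h, 26 of 95 at 20 to 24 h and 18 of 34 in pupae, with 0 reversed. The cause was not tested for any change below unless stated.

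With an estimated correlation 1 list was called in each comparison. At 4 to 8 h, 830 of 7594 tested genes were called when only the groups compared were fitted, and 1146 to 2354 with a library left out (1146 without 0 to 1 h, 2354 without 3 to 4 h). The split of 924 higher and 848 lower turned to 1141 and 1213 without 3 to 4 h, 678 and 724 without 6 to 7 h, 716 and 795 with a constant of 4, 892 and 938 with edgeR, and 1105 and 1387 with 0 to 2 h alone as the early group. Called lists at 20 to 24 h ranged from 6 (without 12 to 13 h) to 12, with 7 without 20 to 21 h. At 20 to 24 h the split of 1253 higher and 1674 lower genes turned to 1809 and 866 with median-of-ratios scaling, 1375 and 812 with edgeR and 1548 and 808 with DESeq2. In pupae, 80 genes were called with no minimum, 0 with edgeR (779 at an unadjusted p below 0.05), 440 with DESeq2, and 33 to 607 with a library left out. Leaving out L1, L2, L3 dark, light and clear gut larvae gave 58, 42, 53, 59 and 607, and the pupae of 1 to 5 days 366, 45, 33, 41 and 240. The split of 80 higher and 82 lower turned to 418 and 189 without L3 clear gut larvae, 231 and 135 without pupae of 1 day, 163 and 77 without those of 5 days, 89 and 63 with a robust prior, and 141 and 81 without CG17298. It was 5 and 28 without pupae of 3 days and 6 and 35 without those of 4 days. Both strands gave 5663 genes and 4 lists, by construction, since minus-strand values were 0.

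Transposon counts at 4 to 8 h ranged from 23 (without 5 to 6 h) to 45 with a library left out, and the split of 10 higher and 26 lower was 13 and 14 without 7 to 8 h. At 20 to 24 h they were 11 with scaling (5 higher and 6 lower, against 1 and 7), 14 and 21 with constants of 4 and 300, 16 without MDG1_I, and 0 to 9 with a library left out, limma calling 0 without 12 to 13 h, 13 to 14 h or 22 to 23 h (32, 34 and 28 at an unadjusted p below 0.05). In pupae they were 1 with constants of 0.25 or 300, 0 with a minimum of 1000 (11 unadjusted) or with scaling (25 unadjusted), and 0 to 5 with a library left out: 0 without L2 or pupae of 3, 4 or 5 days (21, 16, 19 and 17 unadjusted), 1 without pupae of 2 days or an L3 library, and 5 without pupae of 1 day or another L3 library. Between males and females, 1933 genes and 30 transposon classes differed at least 8-fold, 1480 genes reached 50 RPM in the higher sex, and 14 classes were left with a constant of 300. Above the median score 14446 of 15572 peaks overlapped a genic peak. Scaling of transposons by factors of the gene table was not run because the tables have different totals. In the simulated reads 13 of 51 genes changed 2-fold were called under the settings of the earliest comparison. Changes of this size were thus often missed even where the libraries of a group had the same mean.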

Other observations

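The comparison of X and autosomal genes was chosen before its result was seen, and the tests of a shift of all X genes and of peak widths after. Larval serum protein genes were highest in L3 dark gut larvae, and glue and heat shock genes both in L3 clear gut larvae. The 5 plus-strand serum protein genes summed to 192.8 in L1, 181500 in L3 dark gut and 37790 in L3 clear gut larvae, in RPM of the plus-strand reads, and to 4503 in pupae of 5 days. Glue genes summed to 4150 in L3 dark gut, 80970 in L3 light gut and 134600 in L3 clear gut larvae, and to 203.6 in pupae of 2 days. Heat shock genes summed to 1638 in L3 light gut larvae, 35150 in L3 clear gut larvae, 32750 in pupae of 1 day and 1566 in pupae of 5 days, and Hsp27 was the highest plus-strand gene of pupae of 1 day (23114.9 RPM).

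Pupal days also differed in other groups. Antimicrobial genes summed to 5241 in pupae of 1 day and 236.6 in pupae of 5 days. Ecdysone response genes summed to 6980 in pupae of 3 days and 693.8 in pupae of 2 days. Muscle genes fell from 42450 in L1 to 4841 in pupae of 2 days and reached 49680 in pupae of 5 days. Over both strands, the highest gene of L3 light gut larvae was the cuticle gene Lcp2 (127136.6 RPM of all genic reads). In pupae, where minus-strand genes were at 0, the highest plus-strand genes were the cuticle gene Cpr72Ea at 2 days (44426.5), Osi3 at 3 days (51445.6), CG42323 at 4 days (60181.0) and CG17298 at 5 days (425556.5), in RPM of the plus-strand reads. Each of these is a value of 1 library.

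Genes on the X were less often higher in males. Of 1398 X genes 204 (14.59%) were higher in males, against 1681 of 7442 autosomal genes (22.59%; odds ratio 0.5855, Fisher's exact test, two-sided p = 4.39e-12). A lower male value of all X genes may account for part or all of this and stays open. After the log2 ratios of X genes were moved up by 0.532, the difference of the medians of all X and autosomal genes, 18.53% of X genes were higher in males. That is 4.06 percentage points below the autosomal share (95% bootstrap interval over genes 1.9 to 6.13 below). These medians include the genes higher in either sex, so they do not measure such a shift apart from the pattern. Over genes called in neither sex the median was -0.514 for 971 X genes and -0.295 for 4948 autosomal genes, a smaller difference. Those genes were chosen by the ratio itself, so their medians do not measure the shift either. X genes were more often higher in females (15.95% against 10.92%, odds ratio 1.547, Fisher's exact test, p = 2.22e-07). A shortage of testis genes on the X may contribute and was not tested. Genes are not independent, and each sex had 1 library.

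Genes with a short period of high signal in the embryo had narrower peaks. The strongest peaks of 547 such genes (highest hour at least 5 times the mean) had a median width of 87 bp, against 125 bp for 1221 genes whose highest hour stayed below 2 times the mean (permutation test, two-sided p = 1e-05, the smallest that 100000 permutations can give). The peaks were narrower in 5 of 5 bins of mean RPM. Peak widths come from the whole series and each bin spans a range of RPM, so this does not settle whether lower expression is the cause.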
